A study of Rattus norvegicus with 6 samples.

How the data were processed

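Gene expression was measured on 6 arrays of 1185 probes, 1 per sample of soleus muscle from young female Wistar rats that had been hindlimb suspended for 14 days and reloaded for 1 day. Per the labels, total RNA was extracted from frozen sections with a spin column kit (RNeasy) and 5 micrograms were used per array. The values deposited by the authors are intensities on a linear scale, as whole numbers that reach below 0, which shows that a background was subtracted. Each array held 223 to 348 values below 0. The array platform, the scanner, the software and any scaling between arrays are not given in the sources used here. The number of arrays limits the precision, and no count or depth stands behind an intensity.

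All 6 samples belong to the 1 group the labels give, and replicate numbers follow the order of deposition and carry no pairing. No comparison between groups was possible. Every column of the table was used. Before the data were examined, the floor, the tests, the alternatives, 18 gene lists and the rule for named genes were fixed. That rule named the 10 brightest probes, the 10 with the largest SD, the 5 with the smallest SD among probes above the median signal, and the 3 brightest genes of each list, leaving out probes without a gene name. Probe identifiers were looked up among the symbols, synonyms, gene identifiers and accessions of 47357 rat genes (RefSeq, assembly GRCr8), and 0 of 1185 matched. No probe therefore fell under the rule, and the tests of whether the genes of a list vary together, or whether 2 lists correlate over the samples, were not run. Muscle fibre, blood, immune, vessel, nerve, fat and satellite cell markers were among these lists and likewise gave no value. A planned test of ratios against a reference was not run because the table holds intensities.

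The floor was 0, and a probe was measured when it was above the floor on all 6 arrays. The median intensity of probes above 0 differed 1.39-fold between arrays, more than the 10% set as the limit for using the values as deposited, so log2 intensities of the measured probes were quantile normalized with limma 3.58.1 in R 4.3.3. Agreement was Pearson's r across probes for each of the 15 pairs of arrays. For the variance test, the variance of each probe (5 residual degrees of freedom) was set against limma's robust prior variance with a trend on mean log2 intensity (fitted prior degrees of freedom 6.14), as a one-sided F test with Benjamini-Hochberg adjustment and a threshold of 0.05. The test was run on 20 simulated data sets made from the real probes' means and fitted variances, with the SD of some of the 603 probes raised by known factors. A first simulation raised 200 probes by factors of 2 to 6, and the test recovered 0% of them. The simulation was then repeated with 40 probes raised by factors of 3 to 20, a change made after the first result was seen. In that repeat the test recovered a median of 6.52 prior degrees of freedom where 6.14 had been put in, and called 0.35 probes on average where no SD had been raised. Where the simulated prior degrees of freedom were 50, it found 56% of probes raised by a factor of 3.

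The alternatives were another floor (2 times the lowest decile of the values above 0), a probe above 0 on at least 4 arrays, unscaled values, arrays divided by their medians, only the probes above the median signal, all probes with values below 0 set to 0 and a pseudocount of 83 units, a prior variance that was not robust or had no trend, and each replicate left out in turn. A noise floor, the 95th percentile of the size of each array's values below 0, was added after seeing the data. Outlying samples were sought with Dixon's test for 6 values (critical value 0.625), and probe order was tested against 10000 random orders of the identifiers.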

Results

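The expression of 1185 array probes was measured in rat soleus muscle, a slow postural muscle of the hindlimb, after a period of unloading and a short return to weight bearing. Young female Wistar rats had been hindlimb suspended, a procedure that lifts the hind legs off the floor, for 14 days and then reloaded for 1 day. The 6 arrays form 1 group, with 6 replicates and 5 micrograms of total RNA each. No suspended animals without reloading and no ambulatory controls were analysed here. The data therefore describe the reloaded state and the spread between its samples, and give no direction of change for any transcript. The labels do not say whether the 6 samples came from 6 animals, so the variance test concerns only the spread between these samples, which may be technical. The permutation p-values rest on random orders of the probe identifiers and do not measure that spread. The deposited table identifies probes by catalogue numbers (702 beginning with R and 483 beginning with RG) and does not pair them with genes. None of these identifiers matched a rat gene symbol, synonym or accession, and the 18 lists of muscle, matrix, immune, nerve, vessel and metabolic genes fixed beforehand could not be applied.

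Not all of the array was measured in every reloaded soleus sample. A probe counted as measured when its background-subtracted intensity was above 0, and 603 of 1185 probes (50.89%) met this on all 6 arrays. Another 547 probes were above 0 on some arrays only, and 35 were at or below 0 on all 6. The number above 0 per array was 909.5 ± 50.8 (SD, n = 6). It was lowest in replicate 5, with 836 probes, and highest in replicate 3, with 962. Counts in replicates 4 and 6 were 878 and 884, and those in replicates 1 and 2 were 944 and 953. The median intensity of the probes above 0 was 1529 ± 192 units (SD, n = 6), from 1318.5 in replicate 5 to 1839 in replicate 2. An intensity just above 0 is weak evidence for a transcript. The values below 0 on each array gave a noise floor of 4597 ± 1680 units (SD, n = 6), the 95th percentile of their size, and 151 probes exceeded it on all 6 arrays.

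The signal of the reloaded soleus was concentrated in few probes. The 10 brightest probes of an array held 52.3% ± 3.42 (SD, n = 6) of all signal above 0, and the single brightest held 16.53% ± 4.13 (SD, n = 6). The brightest probe was the same on 4 of the 6 arrays, and 6 probes were among the 10 brightest on every array, out of 16 that reached the top 10 on any. The deposited intensity of that most frequent brightest probe ranged 7.13-fold, from 511851 units in replicate 4 to 3647393 units in replicate 2, and 3.54-fold without replicate 4. After quantile normalization its SD was 0.99 on the log2 scale and 0.55 without replicate 4. Its adjusted p over all 6 arrays was 0.776 in the F test of its variance against limma's prior variance for probes of like signal. Quantile normalization gives the brightest probe of every array the same value. This SD and p therefore leave out the spread between those 4 arrays. Brightness depends on the probe as well as on the transcript, so these ranks order spots and not transcript abundances.

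Agreement between the 6 samples was measured over all probes and within classes of brightness. Across the 603 measured probes, Pearson's r of quantile-normalized log2 intensity had a median of 0.861 over the 15 pairs of arrays, with a range from 0.789 to 0.915. These correlations are across probes, which are not independent replicates. The mean r of an array with the others was 0.798 to 0.869 within the brightest tertile of the probes, 0.256 to 0.399 within the middle tertile and 0.129 to 0.306 within the dimmest. Replicate 5 was the lowest array in each tertile, and in the dimmest the other arrays lay between 0.283 and 0.306. An r within a tertile also depends on the range of signal it spans, from 1584 to 6545 units in the middle tertile and from 6561 to 1705000 in the brightest, so these values do not rank the tertiles by reproducibility. The 3 pairs among replicates 1, 2 and 3 gave 0.9005, 0.9113 and 0.9147. Replicate 5 had the lowest mean r with the other arrays, 0.828, whereas the other 5 arrays lay between 0.857 and 0.876. Its r was 0.806, 0.789 and 0.807 with replicates 1, 2 and 3, and 0.861 and 0.875 with replicates 4 and 6. No 2 arrays carried the same values, and at most 3 of the 1185 probes had equal intensities in any pair, so no array was a copy of another. Repeat arrays of the same RNA would also differ in value, so this does not show that the samples are independent. Each array was counted as a sample of its own, as the labels list it.

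**Figure D1:**
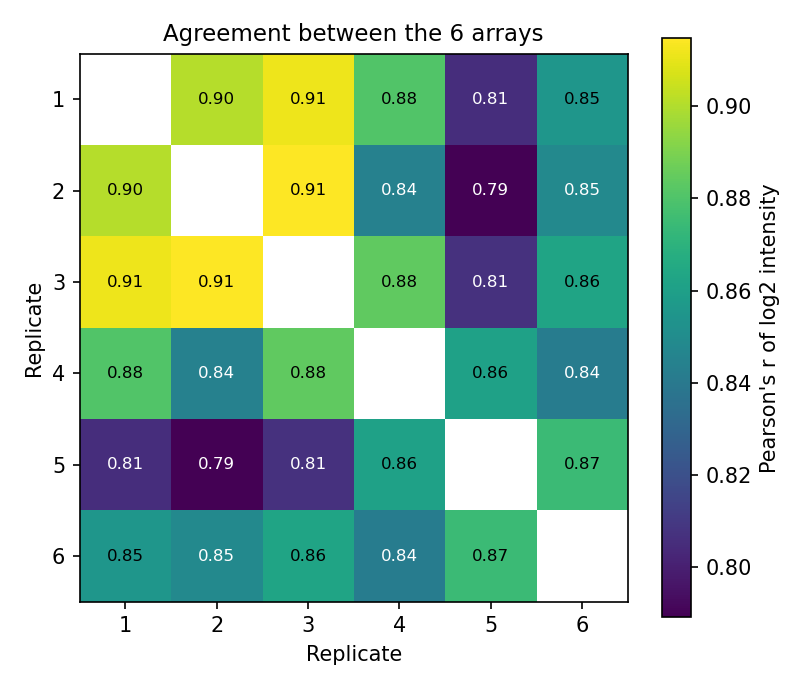
Pearson's r of log2 intensity across 603 probes for each pair of the 6 arrays of reloaded soleus, with replicate numbers on both axes and r given in each cell and by colour. Pairs among replicates 1, 2 and 3 have r from 0.9005 to 0.9147, and replicate 5 has the lowest mean r with the others, 0.828.

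The spread between samples of the same treatment depended on brightness. The median SD over all measured probes was 0.69 on the log2 scale (n = 6), a median coefficient of variation of 44.1%. It was 0.61 without replicate 5, and 0.64 to 0.69 when another replicate was left out. Over all 6 arrays it was 0.99 in the dimmest tertile of 201 probes, with geometric means from 95.02 to 1577 units. In the middle tertile it was 0.61, and in the brightest tertile, above 6561 units, it was 0.52. With these SDs a mean of 6 samples has a typical 95% confidence interval of a factor of 2.06 in either direction in the dimmest tertile, 1.56 in the middle and 1.46 in the brightest. These intervals treat the 6 arrays as independent samples, which the labels do not show, so they may not give the precision of a treatment mean. All geometric means of the dimmest tertile lay below the lowest noise floor of any array, 2618.8 units. Only 151 of the 603 measured probes exceeded the noise floor on all 6 arrays. For the others these SDs and intervals may reflect background noise. Probes at or below 0 on any array are left out, so the SDs of dim probes cover only those that stayed above 0.

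No probe passed the test for a larger spread between the 6 samples than probes of like signal have. The variance test is an F test of each probe's variance against limma's fitted prior variance, which follows a trend over all measured probes. It called 0 of 603 probes at an adjusted p of 0.05 (Benjamini-Hochberg), and the smallest adjusted p was 0.307. At an unadjusted p of 0.05 the test gave 40 probes, against 30.2 from chance and, in simulated data with no raised SD, a mean of 32.8 and a highest count of 42. The same count was 34 with a prior variance that was not robust and 25 with a prior variance without a trend, and both fits also called 0 probes after adjustment. The prior was fitted to these same variances. A count near that from chance is therefore partly set by the fit and does not show a spread at chance level. The test was weak. On simulated data for these 603 probes, with the SD of 40 raised, it found 7.5% of those raised by a factor of 3, 42% at a factor of 6 and 74% at a factor of 10. With the SD of 200 probes raised by factors of 2 to 6 it found none (0%), so the absence of calls does not exclude a larger spread in many probes.

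**Figure D2:**
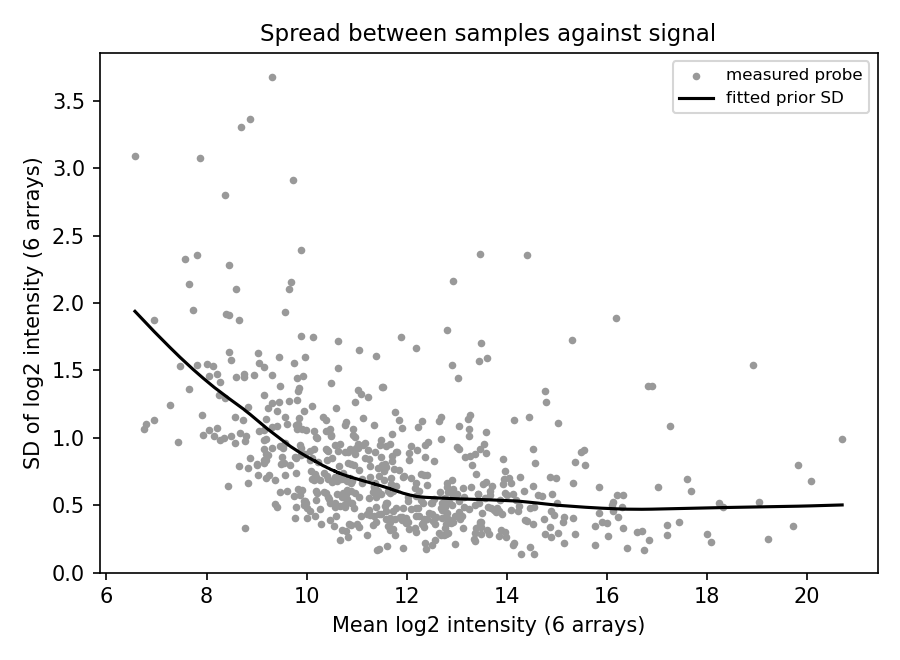
SD of log2 intensity over the 6 arrays (vertical axis) against mean log2 intensity (horizontal axis) for the 603 measured probes, each a point, with limma's fitted prior SD as a line. The spread falls from a median SD of 0.99 in the dimmest tertile to 0.52 in the brightest, and no point passed the variance test.

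The extremes of this spread are shown by 4 probes, chosen after their values were seen because the rule for named genes covers only probes with a gene name. Under quantile normalization the largest SDs belonged to probe RG379, with 3.68 on the log2 scale, and probe R711, with 3.37 (n = 6 each). Neither passed the variance test (F test, adjusted p = 0.384 and 0.392). Both probes lay below the noise floor on all 6 arrays, and 1 array set most of each SD. RG379 had a deposited intensity of 35 units in replicate 3, against 197 to 3564 on the other arrays, and its SD without that replicate was 1.5. R711 had 1 unit in replicate 2, against 553 to 2210 elsewhere, and its SD without that replicate was 1.12. As deposited their SDs were 2.65 for RG379 and 4.21 for R711, after division by medians 2.78 and 4.37, and with all probes and a pseudocount 2.12 and 1.83, so neither their size nor their order is fixed. Among the measured probes above the median signal, R105 and R092 varied least. R105 had a normalized intensity of 23980 ± 2280 units and R092 of 20070 ± 2000 units (SD, n = 6), with ranges over the arrays of 1.28-fold and 1.34-fold. Their log2 SDs, 0.14 each, rose to 0.37 and 0.40 when the arrays were instead divided by their medians. They changed little as deposited, at 0.16 for R105 and 0.135 for R092, or with all probes and a pseudocount, at 0.142 and 0.141.

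**Figure D3:**
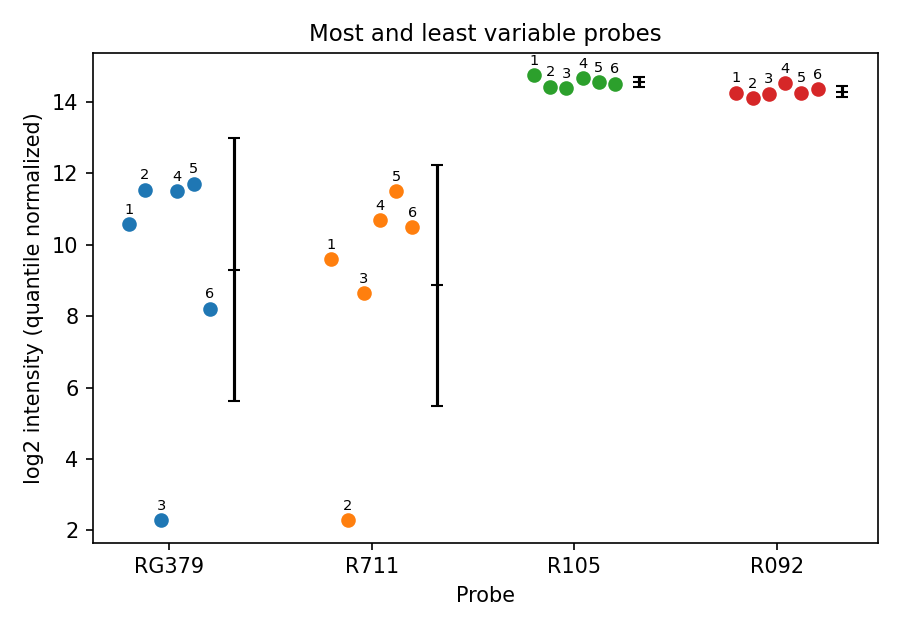
Quantile-normalized log2 intensity (vertical axis) of 4 probes (horizontal axis) on the 6 arrays, with replicate numbers above the points and the mean ± SD as a bar beside them. RG379 in replicate 3 and R711 in replicate 2 lie at 2.28, far below the other arrays, whereas R105 and R092 stay within 1.28-fold and 1.34-fold.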

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

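Of 11 measures per array (7 of the whole array and the log2 signal of 4 probes), 2 had a sample far from the others by Dixon's test, which flags about 1 in 20 groups by chance. Probe RG379 had a log2 signal of 2.282 in replicate 3, against 8.20 to 11.70 on the other 5 arrays. Probe R711 had 2.282 in replicate 2, against 8.64 to 11.50. Both probes were picked for their large SD, so a distant sample is likely by that choice alone, and both lay below the noise floor on all 6 arrays. The value 2.282 is the one that quantile normalization gave to deposited intensities of 35 and 1 units alike. On log2 of the deposited values, a check added after seeing the data, RG379 no longer stood apart (gap over range 0.374, against the critical 0.625), whereas R711 did (0.82). Without these samples the SDs were 1.5 and 1.12. Over all 603 measured probes the same test flagged 54, or 8.96%. Replicate 5 was the distant sample in 17 of these, and the other replicates in 5 to 11 each.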

How the results depend on the processing

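The count of probes above the floor on all 6 arrays was 603, and it fell to 151 with the noise floor taken from values below 0, an alternative chosen after seeing the data whose higher floor is the reason. It was 481 with a floor of 2 times the lowest decile and 876 when 4 of 6 arrays sufficed. Leaving out 1 replicate gave 614 to 659 probes, the highest without replicate 5. The median r between arrays was 0.861 and stayed between 0.848 and 0.885 under every alternative run. The variance test called 0 probes under each of the 7 other settings run and without each replicate, with 33 to 40 probes at an unadjusted p of 0.05 in the 6 runs that left out a replicate. Neither RG379 nor R711 passed the test under any setting that kept them, while their SDs ran from 1.5 to 4.2 and from 1.12 to 4.37; R105 and R092, chosen for small SDs, could not have passed it. The 0 calls say little about stability, since on simulated data the test found 42% of probes with an SD raised by a factor of 6 when 40 were raised, and 0% when 200 were. No paired analysis was possible because there is 1 group. The alternatives for gene lists, for a reference ratio and for count models were not run, for lack of gene names, ratios and counts. The spread was largest among the dim probes, with a median SD of 0.99 in the dimmest tertile under quantile normalization. It was 1.03 as deposited and 1.03 after division by medians, whereas the brightest tertile had 0.52, 0.52 and 0.57. Whether signal over background is the reason was not tested.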

Other observations

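The tests of the order of probe identifiers were chosen after the pattern was seen; the others had their predictions written first, before their values were known. For the test of replicate 5 and both tests of neighbouring probes the written criteria would have excluded the explanation, and they were made stricter after the values were seen, which leaves all 3 open. Tests of why probes were variable had also been planned and were not run, because no probe was called.

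As a ratio, the deposited arrays differed more at the median than at the 90th percentile of their values. The median over all 1185 probes ran from 474 to 1132 units, a ratio of 2.39 between the highest and lowest array. The ratio was 1.61 at the 75th percentile and 1.18 at the 90th. In units the gap between arrays grew from 240 at the 10th percentile to 2277 at the 90th. Only 3 probes were more than 10 times above the noise floor on 1 array or more and at or below 0 on another.

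Replicate 5 had the lowest mean r with the other arrays, a position that falls to 1 of 6 arrays in any case. Dixon's test did not flag it (gap over range 0.598, against 0.625). Its mean Spearman's rho over all 1185 probes was also the lowest, at 0.755 against 0.806 to 0.822. In the dimmest tertile its mean r was 0.129 against 0.283 to 0.306, and on unscaled values 0.825 against 0.847 to 0.881. Dixon's test was not run on these values. By a related count, replicate 5 was the array farthest from the mean of the others in 24.2% of the 603 probes. Replicate 6 followed with 20.4%, and the other 4 arrays had 10.4 to 17.4%. The smaller number of probes above background in replicate 5 stays open as a reason. In the brightest tertile its mean r was below the mean of the other 5 by 0.0411 (bootstrap over probes, 95% interval 0.0119 to 0.0746), but the array had been picked as the lowest over probes that include these, and its gap to the next array there was only 0.297 of the range of the 6 arrays. A difference between animals and a difference in hybridization also stay open, and no biological explanation was tested, as the labels give no further grouping. Replicates 1 to 3 and 4 to 6 differed without overlap in probes above 0, at 944 to 962 against 836 to 884. Noise floors were 4736.4 to 7115.5 units against 2618.8 to 3927.8. In r the split was less clean, as replicate 4 had 0.8807 with replicate 1 and 0.8419 with replicate 6. This split follows the order of deposition and was seen in the data, not tested. Part of the reported spread may go with that order.

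Probes with consecutive catalogue numbers were weakly related in brightness. Spearman's rho of mean intensity between consecutive identifiers was 0.0798 over 1110 pairs, above the range of -0.0486 to 0.0671 that held 95% of 10000 random orders (one-sided permutation p = 0.0099). This restates a pattern first seen among the brightest probes. Without the 20 brightest, rho was 0.0727 over 1072 pairs, narrowly above the random range of -0.0514 to 0.0682 (one-sided permutation p = 0.0172), so a chance order is argued against only narrowly and the relation is weak. Among the 20 brightest probes, 3 had a neighbour in the same 20, against a median of 0 in random orders, a count still within the range of up to 4 that held 95% of them (one-sided permutation p = 0.0319). If signal spread between neighbouring spots, consecutive probes could also deviate together over the arrays. Pairs holding 1 of the brightest 10% of probes had a mean r of 0.0578 (207 pairs, one-sided permutation p = 0.0463, random orders -0.0566 to 0.0667), while all consecutive pairs had -0.0141. This stays open, because the value lies at the edge of the random orders and the numbers are not known to follow the layout of the array. Related transcripts catalogued side by side would be another reason, which was not tested without gene names. For the 9 probes whose mean lay below 0 by more than the noise floor, the brighter neighbour had a median intensity of 1620 units, inside the random range of 399 to 11300, which leaves a background taken from bright neighbours undecided: the probes are few and their layout is not known.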
